A study of Glycine max with 120 samples.

How the data were processed

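Total RNA of 120 soybean samples, labelled in biotin, was measured on Affymetrix Soybean Genome arrays, with 1 array per sample. The labels give the genotype (PI230970 or Embrapa48), the treatment (SBR or Mock), the time (6, 12, 18, 24, 36, 48, 72, 96, 120 or 168 h) and a replicate number, which make 40 groups of 3. The deposited table holds the intensity as MAS5 signal per probe set on a linear scale, which the authors' software scaled for each array. On these values the mean of each array, after leaving out the lowest and highest 2% of probe sets, was 500.1 to 500.2. No version of MAS5 is given.

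Of the 37763 probe sets, 37593 are for soybean and were analysed. The other 170 (122 AFFX control and 48 rRNA probe sets) were left out of the tests and used for quality checks. A probe set was given a gene from the platform annotation, and symbols were updated by Entrez ID to the reference annotation of genome build Glycine_max_v4.0, which also gave the positions in the report. Of 9047 probe sets with a gene, 370 name several genes and were not used for named genes or lists. Probe sets whose identifiers end in _s_at or _x_at can read several members of a gene family.

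Signals were transformed as log2(signal + 16) and each array was centred on its median over the soybean probe sets. One mean per group was fitted to all 120 arrays with limma 3.58.1 in R 4.3.3 (80 residual degrees of freedom, 5.17 prior degrees of freedom, eBayes with a trend in mean level). The comparisons were SBR against Mock at each time in each genotype, the difference of these changes between genotypes (PI230970 minus Embrapa48), F tests of both over the 10 times, the genotype difference in Mock averaged over the times, and an F test of time in Mock. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. All fold changes in the report are on the log2(signal + 16) scale.

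Gene lists were defined by symbol for isoflavonoid phytoalexins, flavonols and anthocyanins, monolignols, pathogenesis-related proteins, class III peroxidases, glutathione S-transferases, WRKY, ethylene response, MYB and NAC transcription factors, receptor kinases and NB-LRR proteins, salicylate signalling, jasmonate and lipoxygenases, ethylene biosynthesis, cell wall, photosynthesis, cytosolic ribosomal proteins, chaperones, the circadian clock, the cell cycle, root and nodule genes, and seed storage. Lists of at least 5 probe sets were tested with limma's camera (preset correlation 0.01) in an early (6 to 18 h), a middle (24 to 48 h) and a late (72 to 168 h) window, and adjusted over all 162 tests. CHIA1 is in both the isoflavonoid and the pathogenesis-related list. The pathogenesis-related list holds 8 probe sets of CHIA1, OLPa, PR-10 and PR10 only, and not PR1-1. The salicylate list holds 5 probe sets of NDR1A, NDR1b and PAD4 only, and not EDS1 or EDS5. RPS6 and RPS13 are in both the receptor kinase and the ribosomal list, since their symbols match both patterns and do not show which is right.

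The comparisons, lists, windows, thresholds and the rule for named genes were chosen before the data were examined. The rule takes probe sets with 1 gene symbol other than a locus number. For each genotype and window it takes the 4 largest called rises and the 3 largest called falls for which all 3 SBR arrays lie above or below all 3 Mock arrays, which chance gives for 10% of probe sets. It adds the 2 largest of each list in each genotype, the 5 largest differences of response each way and the 4 largest Mock genotype differences each way.

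Alternatives were a pseudocount of 1 or 64, signals as deposited, quantile normalization, only the probe sets whose mean is above the median of the means, the replicate number as a block, only the arrays of the groups compared, eBayes without a trend, an absolute log2 change of at least 1, each array or replicate number left out, and for lists an estimated correlation and fry. Added after the data were seen were leaving out replicate 2, leaving out the 3 arrays with the highest actin 3' to 5' ratio, and matching the lists by synonyms. Arrays of the same replicate number deviated together in all 3 pairs (correlation of residuals over 0.1) at 24 h in PI230970 (0.23 to 0.744), 120 h in PI230970 (0.155 to 0.354) and 48 h in Embrapa48 (0.375 to 0.724). This pairing comes from the data, not the labels, and a paired fit with a block per genotype, time and replicate number (40 residual degrees of freedom) was added for these comparisons. A planned test of probe sets for other organisms was not run, since the identifiers show none. The fit was tested on simulated data: of 100 probe sets changed by a log2 of 1, 48% were recovered at 12 h in PI230970 and 47% at 168 h in Embrapa48, and of those changed by 2, 97% and 93%, with 8 and 4 false calls. The simulated spread was independent for each probe set and array, without the shared deviations of the real arrays. The false calls therefore do not measure those in these data.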

Results

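RNA levels of soybean (Glycine max) were measured on one-colour Affymetrix soybean arrays in 120 samples of total RNA. The samples cover 2 genotypes, PI230970 and Embrapa48. Each was given soybean rust (SBR, the disease caused by the fungus Phakopsora pachyrhizi) or a mock treatment (Mock), at 10 times from 6 to 168 h, with 3 arrays in each of the 40 groups. PI230970 is known as a source of rust resistance, and Embrapa48 as a susceptible cultivar. The comparisons ask which genes respond to the rust at each time in each genotype, whether that response differs between the genotypes, and how genotype and time alter RNA levels in Mock plants. Positions of genes are on build Glycine_max_v4.0. Each array gave a signal for 37593 soybean probe sets, of which 9047 had a gene in the annotation and 1676 had a gene symbol other than a locus number. The correlation of an array with the others of its group ranged from 0.903 to 0.987, with a median of 0.977. The number of arrays limits the precision of each comparison. The labels do not say whether the replicates of a group are separate plants, so the p-values measure only the spread between samples. Poly-A spike probe sets read 1.61 to 4.18 on the log2 scale on the 40 arrays of replicate 2, against 8.85 to 10.7 for replicate 1 and 9.51 to 11.3 for replicate 3. Replicate 2 thus forms a batch that holds every group once.

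Named genes that rose under rust at 12 h in PI230970 include PR-10, PRX4, HSP90A1, CHS8 and NAC018. PR-10 (Entrez gene 547915, chromosome 7, 42656819 to 42657703), of the pathogenesis-related protein family 10, was 14.7-fold higher in SBR (log2 change 3.87, SE 0.99, adjusted p = 0.015). Its log2 level was 10.31 ± 1.34 against 6.44 ± 0.67 in Mock (SD, n = 3). PRX4 (Entrez gene 547550, chromosome 16, 32498965 to 32501879), a class III peroxidase, was 13.4-fold higher (log2 change 3.74, SE 0.57, adjusted p = 2.6e-05). Its level was 9.94 ± 0.91 against 6.20 ± 0.43. HSP90A1 (Entrez gene 100811234, chromosome 9, 33674709 to 33678131), a cytosolic chaperone, was 8.49-fold higher (log2 change 3.09, SE 0.65, adjusted p = 0.0021). CHS8, a chalcone synthase at the entry to flavonoid and isoflavonoid synthesis, rose by 2.59 (SE 0.59, adjusted p = 0.0052). The transcription factor NAC018 rose by 2.49 (SE 0.44, adjusted p = 0.00018). Falls were smaller. SS, a sucrose synthase, changed by -1.30 (SE 0.35, adjusted p = 0.022). IFR1, of the isoflavone reductase family, changed by -1.28 (SE 0.38, adjusted p = 0.046) and SSTP-1 by -0.98 (SE 0.29, adjusted p = 0.043). The last pair had log2 levels of 4.24 and 4.52 in SBR, near the floor that the pseudocount sets. Their changes were -2.93 and -2.42 with a pseudocount of 1, and -0.53 and -0.38 with 64. With limma, 952 probe sets passed, 733 higher and 219 lower in SBR. An unadjusted p under 0.05 was seen for 6130, where chance gives 1880 if all groups share 1 spread. The count was 353 without SBR replicate 1, 219 without SBR replicate 2, and 607 without Mock replicate 3. It was 222 when only the 6 arrays compared set the spread (221 higher and 1 lower). It was 21 without replicate 2 of every group, where 8 were higher and 13 lower, so the balance turned. PRX4, HSP90A1 and NAC018 passed with each of the 6 arrays left out in turn. PR-10 did not without SBR replicate 1 (adjusted p = 0.15), SBR replicate 2 (0.088) or Mock replicate 1 (0.065), nor CHS8 without SBR replicate 1 (0.059) or 2 (0.06). SS did not without SBR replicate 1 (0.089) or 2 (0.25) or Mock replicate 1 (0.072) or 3 (0.077). IFR1 did not without SBR replicates 1 (0.14), 2 (0.17) or 3 (0.072) or Mock replicates 1 (0.17) or 3 (0.32). SSTP-1 did not without SBR replicates 1 (0.25) or 3 (0.097) or Mock replicates 1 (0.23) or 3 (0.1).

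Members of the isoflavonoid, WRKY, glutathione S-transferase, chaperone and peroxidase lists rose at 12 h in PI230970. Of 61 probe sets of the isoflavonoid pathway, which makes soybean phytoalexins, 19 rose and 1 fell (24 and 1 adjusted over the list alone). Of 103 probe sets of WRKY transcription factors, a family with known roles in plant defence, 25 rose and none fell (43 and 1 adjusted over the list alone). Among them were WRKY56 (log2 change 2.28, SE 0.39, adjusted p = 0.00012) and WRKY19 (2.09, SE 0.39, adjusted p = 0.00037). Among 42 probe sets of glutathione S-transferases, enzymes that conjugate toxic compounds, 12 rose (16 rose and 2 fell adjusted over the list alone). They include GSTU13 (2.33, SE 0.41, adjusted p = 0.00024) and GSTU42 (2.08, SE 0.56, adjusted p = 0.023). Heat shock proteins and chaperones had 12 of 18 probe sets that rose (13 adjusted over the list alone), including HSP23.9 (2.32, SE 0.49, adjusted p = 0.0019). The class III peroxidases had 3 of 6 that rose (3 rose and 1 fell adjusted over the list alone). The pathogenesis-related proteins had 2 of 8 (4 adjusted over the list alone), and the NAC family 1 of 30, NAC018 (1 adjusted over the list alone). MYB transcription factors had 2 of 102 that rose (4 adjusted over the list alone), 1 of them MYB29 (1.88, SE 0.55, adjusted p = 0.044). None of 5 probe sets for salicylate and EDS1-PAD4 signalling and none of 10 for cytosolic ribosomal proteins passed over all probe sets, while 3 and 6 rose adjusted over the list alone. Medians were negative, without a called fall, for cell wall genes (-0.49), root and nodule genes (-0.33), photosynthesis (-0.30) and the flavonol branch (-0.28). They were also negative for the jasmonate (-0.26), clock (-0.23), receptor kinase (-0.17), seed storage (-0.09) and MYB lists (-0.08). After quantile normalization these 9 medians were, in the same order, -0.38, -0.17, 0.01, -0.31, -0.20, -0.09, -0.09, -0.03 and -0.04. The median over all probe sets was -0.07 before and -0.03 after it, so the seed storage and MYB medians lie close to that of all probe sets. The receptor kinase and ribosomal lists share RPS6 and RPS13. The call of GSTU42 was lost without SBR replicate 1 (adjusted p = 0.14), SBR replicate 2 (0.14) or Mock replicate 2 (0.13). That of MYB29 was lost without SBR replicate 1 (0.12), SBR replicate 2 (0.25), Mock replicate 2 (0.087) or Mock replicate 3 (0.17).

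Over the early window of 6, 12 and 18 h in PI230970, the isoflavonoid, pathogenesis-related, peroxidase, glutathione S-transferase, WRKY, NAC, ribosomal and chaperone lists were higher than other probe sets by camera with a preset correlation. None of these calls held with an estimated one. The medians of the log2 change were 0.43 for the isoflavonoid list (adjusted p = 4.7e-12, and adjusted p = 0.12 with an estimated correlation). They were 1.16 for pathogenesis-related proteins (adjusted p = 3.8e-09, and adjusted p = 0.11 with an estimated correlation) and 0.34 for the WRKY family (adjusted p = 1.2e-21, and adjusted p = 0.063 with an estimated correlation). The peroxidase median was 0.87 (adjusted p = 0.00033, and adjusted p = 0.063 with an estimated correlation). It was 0.09 for glutathione S-transferases (adjusted p = 7.9e-05, and adjusted p = 0.17 with an estimated correlation) and 0.38 for the NAC family (adjusted p = 2.1e-08, and adjusted p = 0.17 with an estimated correlation). For ribosomal proteins the median was 0.29 (adjusted p = 0.00038, and adjusted p = 0.41 with an estimated correlation). For chaperones it was 0.41 (adjusted p = 0.00084, and adjusted p = 0.45 with an estimated correlation). Of the 162 list tests in both genotypes and in their difference, 53 passed with the preset correlation (38 higher and 15 lower), 5 with an estimated one and 17 by fry. The fry test asks only whether the members of a list move on balance 1 way. Random splits of the arrays gave a median of 27 and up to 48 calls with the preset correlation, so its p-values cannot be taken at face value. Such splits can still hold a part of the real change, so they do not measure how far the p-values are off.

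Apart from 12 h, few probe sets were called at any single time in PI230970. An unadjusted p under 0.05 was seen for 4802 at 6 h and 2838 at 72 h, where chance gives 1880 if all groups share 1 spread. The other times but 12 h had fewer. The spread was not equal: the PI230970 Mock 6 h arrays correlated with their group mates at 0.947 or less, against a median of 0.977. Another split of the SBR and Mock arrays at 6 h called 159 probe sets against the real 9. The excess over 1880 at 6 h therefore does not show a response to the rust. At 6 h CHS1 (Entrez gene 732575, chromosome 8, 8392290 to 8393861), a chalcone synthase, was 9.02-fold higher in SBR (log2 change 3.17, SE 0.60, adjusted p = 0.0093). It was at 10.22 ± 1.64 against 7.04 ± 0.85 (SD, n = 3). At 168 h OLPa (Entrez gene 100037479, chromosome 11, 1804440 to 1805753), an osmotin-like protein of the pathogenesis-related family 5, was 6.71-fold higher (log2 change 2.75, SE 0.55, adjusted p = 0.0073). PTS-L5 was 3.85-fold higher (1.94, SE 0.44, adjusted p = 0.036) and PR1-1, of the pathogenesis-related family 1, 3.13-fold higher (1.64, SE 0.38, adjusted p = 0.048). Of the 8 probe sets of pathogenesis-related proteins, 3 rose at 168 h (7 adjusted over the list alone). Of the isoflavonoid list 1 rose at 6 h (17 rose and 2 fell adjusted over the list alone). In these data limma called 9 probe sets at 6 h (8 higher), 1 at 24 h, 5 at 72 h (3 higher), 2 at 96 h (both higher), 16 at 120 h (15 higher) and 32 at 168 h (31 higher). The F test over the 10 times called 333, and 130, 36 and 174 without replicate numbers 1, 2 and 3. In a paired fit the counts were 0 at 24 h (944 with an unadjusted p under 0.05) and 25 at 120 h. With limma 0 were called at 18, 36 and 48 h, where 933, 1193 and 663 probe sets had an unadjusted p under 0.05. Chosen after its values were seen, LOC100500690 was 1 of the 2 at 96 h (1.96, SE 0.39, adjusted p = 0.042). The other call at 96 h, the call at 24 h (log2 change -1.94) and those at 72 h (-0.84 to 2.54) are probe sets with no gene in the annotation. PI230970 Mock 6 h replicates 3 and 1 stood apart on the leading axis of the spread between replicates, with scores of 98.9 and -65.5. Negative scores lie toward the end of this axis that holds PR-10. Mock 6 h replicate 1 had an actin 3' to 5' log2 ratio of 1.98 against a median of 1.29.

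These smaller counts in PI230970 depended on single arrays. At 6 h the count was 0 without SBR replicate 2 or Mock replicate 3, 1661 without Mock replicate 1 and 423 without Mock replicate 2. CHS1 did not pass without SBR replicate 2 (adjusted p = 0.41) or Mock replicate 3 (0.48). At 168 h it was 21 without SBR replicate 1, 17 without SBR replicate 2, 8 without SBR replicate 3 and 6 without Mock replicate 1. There OLPa did not pass without SBR replicate 3 (adjusted p = 0.42) or Mock replicate 1 (0.39). PTS-L5 did not without SBR replicates 1 (0.082), 2 (0.094) or 3 (0.68) or Mock replicate 1 (1). PR1-1 did not without any 1 of the 6 arrays (0.063 to 0.89). At 120 h the count was 3 without SBR replicate 1, 7 without Mock replicate 1 or 3 and 184 without Mock replicate 2. At 72 h it was 2 without SBR replicate 2, 3 without SBR replicate 3, 0 without Mock replicate 1 or 2 and 62 without Mock replicate 3. At 96 h it was 1 without SBR replicate 1 or Mock replicate 2 and 0 without any 1 of the other 4 arrays. At 24 h the count was 4 without SBR replicate 1 and 0 without SBR replicate 2, Mock replicate 1 or Mock replicate 2. The counts of 0 became 1 and 3 at 18 h without SBR replicate 3 and Mock replicate 2. They became 3, 2 and 1 at 36 h without SBR replicate 3, Mock replicate 1 and Mock replicate 2.

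**Figure D1:**
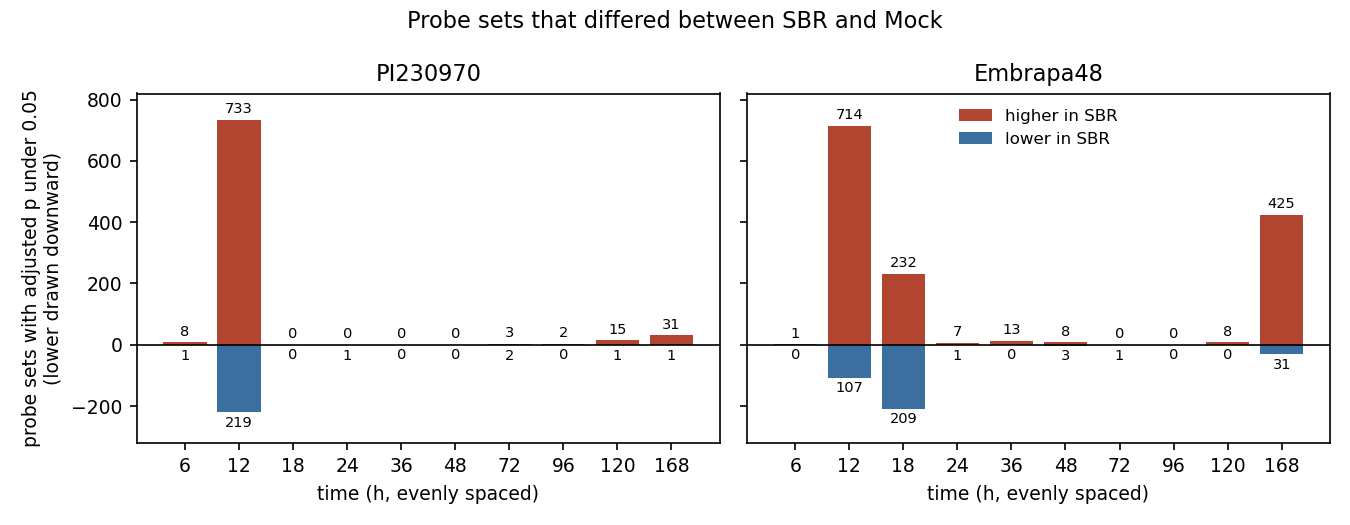
Number of probe sets with an adjusted p under 0.05 between SBR and Mock (vertical axis, lower ones drawn downward) against time in hours, for PI230970 (left) and Embrapa48 (right), 3 arrays per group. The counts of higher probe sets reach 733 and 714 at 12 h, and 31 and 425 at 168 h.

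At 12 h in Embrapa48, CHS1, CHS8, PR-10 and CYP82A3 had the largest named rises. Another probe set of CHS1 was 17.4-fold higher in SBR (log2 change 4.12, SE 0.59, adjusted p = 8.4e-07), at 11.30 ± 0.41 against 7.18 ± 0.91 (SD, n = 3). CHS8 was 12.2-fold higher (3.60, SE 0.59, adjusted p = 1.7e-05). PR-10 was 11.9-fold higher (3.57, SE 0.99, adjusted p = 0.03). CYP82A3 (Entrez gene 100789386, chromosome 13, 15922866 to 15926005), a cytochrome P450, was 11.5-fold higher (3.53, SE 0.43, adjusted p = 1.1e-08). Of the isoflavonoid list 24 of 61 probe sets rose and none fell (31 and 1 adjusted over the list alone). Of the WRKY list 19 of 103 rose (28 adjusted over the list alone), among them WRKY12 (2.31, SE 0.47, adjusted p = 0.00079). The chaperones had 10 of 18 that rose (13 adjusted over the list alone), including HSP90A1 (2.59, SE 0.65, adjusted p = 0.012) and HSP23.9 (1.69, SE 0.49, adjusted p = 0.041). The glutathione S-transferases had 6 of 42 (11 rose and 4 fell adjusted over the list alone), including GSTU13 (3.28, SE 0.41, adjusted p = 4e-08). PRX4 (2.26, SE 0.57, adjusted p = 0.012) was 1 of 2 peroxidases of 6 that rose (3 adjusted over the list alone). Its Mock level of 4.58 is near the floor, and the change was 3.98 with a pseudocount of 1 and 1.13 with 64. NAC018 (2.23, SE 0.44, adjusted p = 0.00041) was the 1 NAC probe set of 30 (1 adjusted over the list alone). PAD4 (1.09, SE 0.31, adjusted p = 0.039), the partner of EDS1 in salicylate-dependent immunity, was 1 of 2 of the 5 salicylate signalling probe sets that rose (4 adjusted over the list alone). Pathogenesis-related proteins had 2 of 8 that rose (7 adjusted over the list alone) and MYB factors 5 of 102 (5 adjusted over the list alone). In all 821 probe sets passed with limma, 714 higher and 107 lower (4909 with an unadjusted p under 0.05). With the signals as deposited the split was 931 and 36, where the median over all probe sets lay 0.10 higher. The count was 416 without SBR replicate 2, 514 without Mock replicate 1 and 410 without Mock replicate 2. It was 426 when only the 6 arrays compared set the spread and 106 without replicate 2 of every group. CHS1, CHS8, CYP82A3, GSTU13, WRKY12 and NAC018 passed with each array left out in turn. The calls of PR-10, PRX4, PAD4, HSP90A1 and HSP23.9 were lost without SBR replicate 1 (adjusted p 0.072 to 0.17). Those but HSP90A1 were lost without SBR replicate 2 (0.16 to 0.21) or Mock replicate 1 (0.066 to 0.24). Those but PRX4 were lost without Mock replicate 2 (0.15 to 0.28), and that of PRX4 without Mock replicate 3 (0.055).

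Over the early window in Embrapa48, the isoflavonoid list rose by camera with either correlation (median log2 change 0.68, adjusted p = 1.1e-38, and adjusted p = 0.00051 with an estimated correlation). So did the pathogenesis-related proteins (1.55, adjusted p = 1e-17, and adjusted p = 0.0083 with an estimated correlation). The WRKY list (0.21, adjusted p = 7.8e-17, and adjusted p = 0.12 with an estimated correlation) passed with the preset correlation alone. So did the chaperones (0.54, adjusted p = 1.1e-11, and adjusted p = 0.072 with an estimated correlation) and the glutathione S-transferases (0.11, adjusted p = 1.4e-07, and adjusted p = 0.063 with an estimated correlation). The NAC family (0.24, adjusted p = 0.00022, and adjusted p = 0.41 with an estimated correlation) did as well. The salicylate list (0.27, adjusted p = 0.0069, and adjusted p = 0.063 with an estimated correlation) and the peroxidases (0.40, adjusted p = 0.013, and adjusted p = 0.24 with an estimated correlation) behaved likewise. The salicylate list covers only NDR1A, NDR1b and PAD4.

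At 18 h in Embrapa48 probe sets changed in both directions, and pathogenesis-related proteins were among those that rose. Of their 8 probe sets 4 rose and none fell (8 adjusted over the list alone). Named falls were CYP77A3, a cytochrome P450 (-1.90, SE 0.53, adjusted p = 0.05 after rounding), and SS, at another probe set (-1.55, SE 0.35, adjusted p = 0.018). FAD3C, an omega-3 fatty acid desaturase, fell too (-1.20, SE 0.28, adjusted p = 0.021, at 4.26 in SBR, near the floor). Its change was -3.05 with a pseudocount of 1 and -0.45 with 64. NAC factors had 1 of 30 that rose (6 adjusted over the list alone), and WRKY factors 1 of 103 (1 adjusted over the list alone). The isoflavonoid, MYB and receptor kinase lists had 1 that rose and 1 that fell each (2 and 1, 3 and 3, and 1 and 4 adjusted over the list alone). With limma 441 probe sets passed, 232 higher and 209 lower (6920 with an unadjusted p under 0.05). The split was 310 and 238 with the signals as deposited. With the replicate number as a block 697 passed, 336 higher and 361 lower, so the balance turned. Embrapa48 Mock 18 h replicate 3 stood apart on the leading axis of replicate spread (score -78.7), and the count was 6028 without it. It was 14 without Mock replicate 1, 6 without Mock replicate 2, and 89, 258 and 60 without SBR replicates 1, 2 and 3. It was 0 when only the 6 arrays compared set the spread or without replicate 2 of every group. The 3 named falls did not pass without SBR replicate 1 (adjusted p 0.075 to 0.16), SBR replicate 3 (0.089 to 0.14), Mock replicate 1 (0.14 to 0.32) or Mock replicate 2 (0.24 to 0.42), nor CYP77A3 without SBR replicate 2 (0.067).

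At 168 h in Embrapa48 probe sets of pathogenesis-related proteins and some of the isoflavonoid list rose. OLPa was 46-fold higher in SBR (log2 change 5.52, SE 0.55, adjusted p = 2.4e-12), at 10.45 ± 1.39 against 4.93 ± 0.81 (SD, n = 3). Its Mock level lies near the floor, so the fold depends on the pseudocount (log2 change 6.89 with 1 and 4.22 with 64). PR-10, at another probe set, was 32.4-fold higher (5.02, SE 0.73, adjusted p = 9.5e-07). GSTU42 rose by 4.41 (SE 0.56, adjusted p = 1.8e-08), IFR, an isoflavone reductase, by 3.43 (SE 0.68, adjusted p = 0.00072). MYB73 rose by 3.22 (SE 0.51, adjusted p = 8.2e-06), MYB184 by 2.65 (SE 0.69, adjusted p = 0.026) and WRKY21 by 2.28 (SE 0.54, adjusted p = 0.0088). All 8 probe sets of the pathogenesis-related list, which cover only CHIA1, OLPa, PR-10 and PR10, rose (8 adjusted over the list alone). Of the isoflavonoid list 19 of 61 rose (26 adjusted over the list alone). So did 4 of 103 WRKY (17 adjusted over the list alone), 4 of 102 MYB (5 adjusted over the list alone) and 2 of 42 glutathione S-transferase probe sets (7 adjusted over the list alone). None of these lists had a member that fell. IQD40, a calmodulin-binding IQ-domain protein, changed by -1.99 (SE 0.52, adjusted p = 0.028) and EDS5, a salicylate transporter, by -0.71 (SE 0.20, adjusted p = 0.049). With limma 456 probe sets passed, 425 higher and 31 lower (4239 with an unadjusted p under 0.05). The F test over the 10 times called 890, and 234, 215 and 1503 without replicate numbers 1, 2 and 3. The count was 206 without SBR replicate 1, 181 without SBR replicate 3, 195 without Mock replicate 2, 214 without replicate 2 of every group and 0 when only the 6 arrays compared set the spread. OLPa, PR-10, GSTU42 and MYB73 passed with each array left out in turn. Calls among IFR, IQD40, EDS5, WRKY21 and MYB184 were lost without SBR replicate 1 (adjusted p 0.063 to 0.14), 2 (0.075 to 0.18) or 3 (0.058 to 0.34). They were also lost without Mock replicate 1 (0.063 to 0.18) or 2 (0.28 to 0.31), and that of MYB184 without Mock replicate 3 (0.051).

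At the other times in Embrapa48 the counts were small. PR1-1 was 4.11-fold higher at 36 h (log2 change 2.04, SE 0.38, adjusted p = 0.0054), at 6.86 ± 0.50 against 4.82 ± 0.47 (SD, n = 3). Its Mock level is near the floor, and the change was 3.38 with a pseudocount of 1 and 1.05 with 64. At 24 h 1-3-1A changed by -1.75 (SE 0.37, adjusted p = 0.048). With limma 1 probe set passed at 6 h, 8 at 24 h (7 higher), 13 at 36 h (all higher), 11 at 48 h (8 higher), 1 at 72 h and 8 at 120 h (all higher). With the replicate number as a block 63 passed at 72 h, 49 higher and 14 lower. With limma 0 passed at 96 h, where 1133 had an unadjusted p under 0.05. Chosen after its values were seen, LOC100820397 was the call at 6 h (1.75, SE 0.33, adjusted p = 0.025). The call at 72 h is a probe set with no gene in the annotation (-2.50, SE 0.45, adjusted p = 0.012). The call at 6 h was lost without SBR replicate 1, Mock replicate 1 or Mock replicate 3 (count 0), and 6 passed without SBR replicate 3. At 24 h the count was 60 without SBR replicate 2, 0 without SBR replicate 3, 1 without Mock replicate 1 or 2 and 5 without Mock replicate 3. 1-3-1A did not pass without SBR replicate 1 (adjusted p = 0.49), SBR replicate 3 (0.49), Mock replicate 1 (0.4) or Mock replicate 2 (1). At 36 h it was 3 without SBR replicate 1 and 1 without SBR replicate 2 or Mock replicate 2, where PR1-1 had adjusted p of 0.095, 0.13 and 0.19. At 48 h it was 1 without SBR replicate 2 or Mock replicate 1, 0 without SBR replicate 3 and 37 without Mock replicate 3. At 72 h it was 0 without SBR replicate 1 or 2 and 9, 88 and 842 without Mock replicates 1, 2 and 3. At 96 h 3 passed without Mock replicate 1 and 1 without Mock replicate 3. At 120 h it was 3, 5 and 1 without SBR replicates 1, 2 and 3 and 13, 2 and 3 without Mock replicates 1, 2 and 3.

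**Figure D2:**
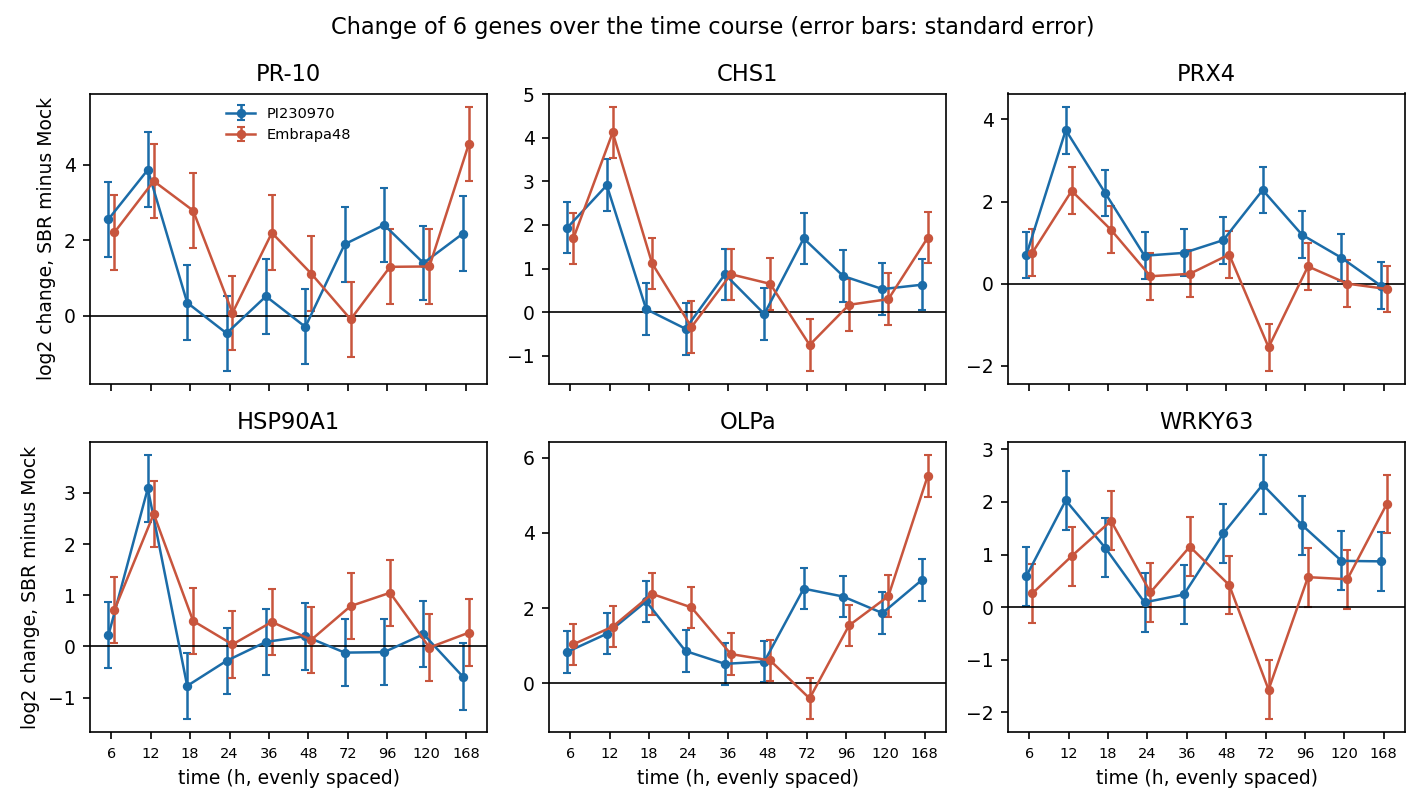
Log2 change between SBR and Mock (vertical axis, error bars SE, 3 arrays per group) of PR-10, CHS1, PRX4, HSP90A1, OLPa and WRKY63 against time in hours in PI230970 and Embrapa48. PR-10 reaches 3.87 and 3.57 at 12 h, and OLPa 2.75 and 5.52 at 168 h.

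In the middle window of 24, 36 and 48 h, the listed pathogenesis-related proteins CHIA1, OLPa, PR-10 and PR10 rose as a list in Embrapa48 (median log2 change 1.13, adjusted p = 3.1e-14, and adjusted p = 0.028 with an estimated correlation). They rose over the late window of 72 to 168 h in PI230970 (2.00, adjusted p = 1e-35, and adjusted p = 2.8e-05 with an estimated correlation) and in Embrapa48 (1.84, adjusted p = 2.7e-42, and adjusted p = 6.3e-06 with an estimated correlation). All other calls of these windows were lost with an estimated correlation. In the late window the isoflavonoid list had medians of 0.16 in PI230970 (adjusted p = 8.8e-11, and adjusted p = 0.17 with an estimated correlation) and 0.19 in Embrapa48 (adjusted p = 2.3e-09, and adjusted p = 0.22 with an estimated correlation). The WRKY list had 0.21 (adjusted p = 2.4e-16, and adjusted p = 0.12 with an estimated correlation) and 0.09 (adjusted p = 6e-11, and adjusted p = 0.25 with an estimated correlation). The jasmonate and lipoxygenase list, which includes the vegetative lipoxygenases, had negative medians in the middle window in PI230970 (-0.20, adjusted p = 1.1e-05, and adjusted p = 0.41 with an estimated correlation) and Embrapa48 (-0.26, adjusted p = 3.9e-05, and adjusted p = 0.45 with an estimated correlation). It had one in the late window in PI230970 too (-0.23, adjusted p = 0.0014, and adjusted p = 0.6 with an estimated correlation). Photosynthesis genes had medians of -0.29 and -0.21 in the middle and late windows in Embrapa48 (adjusted p = 0.0002 and 0.00023, and adjusted p = 0.25 with an estimated correlation for each). The flavonol and anthocyanin branch had a median of -0.30 in the late window in PI230970 (adjusted p = 0.0057, and adjusted p = 0.25 with an estimated correlation). The middle-window NAC median in PI230970 was -0.11 (adjusted p = 0.0093, and adjusted p = 0.62 with an estimated correlation), but 0.08 in replicates 1 and 3 and -0.49 in replicate 2. In the middle window in PI230970 the isoflavonoid list had a median of -0.07 (adjusted p = 0.014, and adjusted p = 0.68 with an estimated correlation) and pathogenesis-related proteins 0.42 (adjusted p = 0.0003, and adjusted p = 0.41 with an estimated correlation). Peroxidases had 0.31 (adjusted p = 0.0082, and adjusted p = 0.2 with an estimated correlation) and glutathione S-transferases 0.08 (adjusted p = 0.022, and adjusted p = 0.47 with an estimated correlation). The WRKY list had 0.05 in Embrapa48 (adjusted p = 0.013, and adjusted p = 0.71 with an estimated correlation). In the late window in PI230970 the medians were 0.28 for peroxidases (adjusted p = 0.036, and adjusted p = 0.34 with an estimated correlation) and 0.11 for glutathione S-transferases (adjusted p = 0.001, and adjusted p = 0.29 with an estimated correlation). They were 0.11 for NAC factors (adjusted p = 0.019, and adjusted p = 0.62 with an estimated correlation) and 0.12 for ribosomal proteins (adjusted p = 0.031, and adjusted p = 0.62 with an estimated correlation). In Embrapa48 the NAC median was 0.11 (adjusted p = 0.0042, and adjusted p = 0.55 with an estimated correlation). It was 0.12 for the salicylate list (adjusted p = 0.014, and adjusted p = 0.11 with an estimated correlation) and 0.15 for chaperones (adjusted p = 0.00092, and adjusted p = 0.45 with an estimated correlation). No probe set of the jasmonate, photosynthesis or flavonol lists passed over all probe sets at any single time in either genotype. The ethylene response factor, MYB, receptor kinase, cell wall, root and nodule, and seed storage lists passed in no window with the preset correlation. The monolignol, ethylene biosynthesis and clock lists, with 2, 4 and 3 probe sets, were too small to test, as was the empty cell cycle list.

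The probe sets that rose at 12 h were largely shared by the genotypes. Of 733 in PI230970 and 714 in Embrapa48, 419 were shared, where 13.9 would be if the sets were independent. Of 219 and 107 that fell 4 were shared (0.623 if independent). All 31 probe sets that rose at 168 h in PI230970 also rose at that time in Embrapa48 (0.35 if independent). Of the rises at 12 h in Embrapa48, 140 of 714 were seen again at 168 h (8.07 if independent). Across probe sets, which are not independent of each other, the log2 changes of the genotypes correlated at 0.61 at 12 h and 0.43 at 120 h, at -0.34 at 6 h and -0.14 at 72 h, and between 0.03 and 0.29 at the other 6 times. The 733 probe sets that rose at 12 h in PI230970 had a median change there of 1.32 at 12 h and -0.07 at 24 h. It was 0.51 in PI230970 and -0.36 in Embrapa48 at 72 h. The 425 that rose at 168 h in Embrapa48 had medians of 0.70, 0.63, 0.60 and 0.74 in PI230970 at 72, 96, 120 and 168 h, and of -0.45, 0.32, 0.41 and 1.81 in Embrapa48. Each set was chosen for its rise at that time in that genotype, which raises its median there. The 1.32 and the 1.81 therefore cannot be set against other times or the other genotype. The difference of response at 168 h passed with limma for 0 probe sets, with 2129 at an unadjusted p under 0.05.

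**Figure D3:**
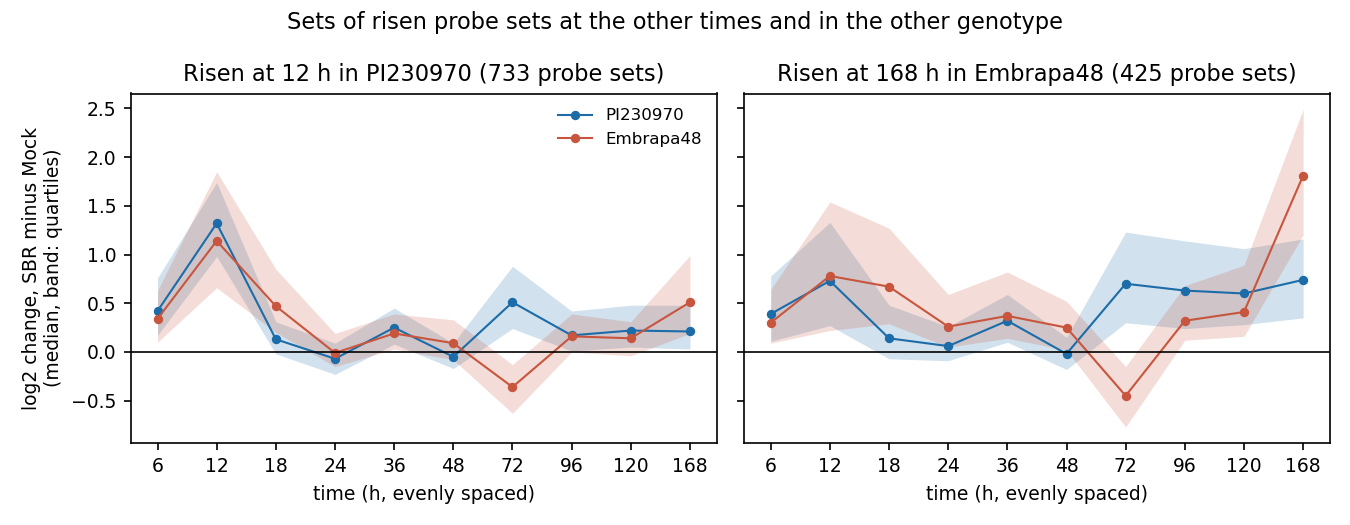
Median log2 change between SBR and Mock (lines; bands, quartiles over probe sets) against time in hours in PI230970 and Embrapa48, for the 733 probe sets that rose at 12 h in PI230970 (left) and the 425 that rose at 168 h in Embrapa48 (right). At 72 h the medians are 0.51 and 0.70 in PI230970 and -0.36 and -0.45 in Embrapa48. Each set was chosen for its rise at the named time and genotype, which raises its median there.

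The rust response differed between the genotypes for more called probe sets at 72 h than at any other time, although more had an unadjusted p under 0.05 at 6 h (5221). The order turned with single arrays left out, which gave up to 1102 calls at 6 h and 285 at 18 h against 82 at 72 h. WRKY63, PRX4, 4CL4, CHI4A and STP had the higher change in PI230970 and MYB186 and SFR2 in Embrapa48. WRKY63 (Entrez gene 100170679, chromosome 17, 37470299 to 37472613), a WRKY transcription factor, had log2 changes of 2.33 and -1.57 in the genotypes (difference 3.89, SE 0.79, adjusted p = 0.039). PRX4 had changes of 2.28 and -1.55 (3.82, SE 0.81, adjusted p = 0.042). The phenylpropanoid enzyme 4CL4, a 4-coumarate:CoA ligase, differed by 2.46 (SE 0.55), CHI4A, of the chalcone isomerase family, by 1.75 (SE 0.40) and STP by 1.67 (SE 0.37). MYB186 differed by -2.00 (SE 0.44) and SFR2 by -1.66 (SE 0.37), with an adjusted p = 0.042 for each of these 5. None of the 7 genes passed at 72 h within either genotype. In the late window the difference did not pass for the isoflavonoid (adjusted p = 0.44), pathogenesis-related (0.93) or WRKY list (0.091) by camera. It passed for the peroxidase (0.045), jasmonate (0.036), ribosomal (0.00044) and chaperone lists (0.00027), but for none of these with an estimated correlation (0.39, 0.72, 0.41 and 0.41). With limma 31 probe sets differed at 72 h, 26 with the higher change in PI230970 and 5 with the lower (4056 with an unadjusted p under 0.05). With log2(signal + 1) 6 differed, 2 with the higher change in PI230970 and 4 with the lower, so the balance turned. With the signals as deposited 1 and 1 passed and after quantile normalization 2 and 1. There the 7 genes kept their direction at adjusted p of 0.075 to 0.093 and 0.052 to 0.087 (0.0035 to 0.36 over the alternatives that keep every replicate number). The median over all probe sets moved by 0.11 between centring and none.

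The 31 calls at 72 h depended on single arrays. The count was 4, 12, 1, 0 and 18 without PI230970 SBR replicates 1 and 3 and Mock replicates 1, 2 and 3. It was 2, 0, 17, 82 and 4 without Embrapa48 SBR replicates 1, 2 and 3 and Mock replicates 1 and 2. All 7 genes failed to pass without PI230970 SBR replicate 1 (adjusted p 0.13 to 0.22), SBR replicate 3 (0.062 to 0.12), Mock replicate 1 (0.097 to 0.21) or Mock replicate 2 (0.081 to 0.12). They also failed without Embrapa48 SBR replicate 1 (0.055 to 0.15) or SBR replicate 2 (0.074 to 0.14). Of WRKY63, PRX4, 4CL4, CHI4A, STP, MYB186 and SFR2, all but SFR2 failed without Embrapa48 Mock replicate 2 (0.06 to 0.1). 4CL4, CHI4A, STP and SFR2 failed without PI230970 Mock replicate 3 (0.062), and these and MYB186 without Embrapa48 SBR replicate 3 (0.054 to 0.093). PRX4, 4CL4, CHI4A and STP failed without Embrapa48 Mock replicate 3 (0.067 to 0.12) and SFR2 without Embrapa48 Mock replicate 1 (0.2). Embrapa48 Mock 72 h replicate 1 had the highest actin 3' to 5' log2 ratio of the 120 arrays, 2.13 against a median of 1.29. Without it and the other 2 arrays of highest ratio 97 probe sets differed at 72 h and 1236 at 6 h, an alternative chosen after the ratios were seen.

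At the other times almost no difference in response passed. With limma the counts were 1 at 6 h, 2 at 18 h and 1 at 36 h, with 5221, 2723 and 1260 at an unadjusted p under 0.05. There was 1 by the F test over the time course (1356 with an unadjusted p under 0.05). They were 0 with limma at 12, 24, 48, 96, 120 and 168 h, where 1332, 551, 761, 714, 674 and 2129 had an unadjusted p under 0.05. Chosen after their values were seen, these are probe sets with no gene in the annotation: 1 at 6 h (-2.74), 2 at 18 h (-1.61 and -1.68), 1 at 36 h (1.18) and 1 over the time course (adjusted p = 4.9e-05). The last had a difference of -2.75 at 36 h. At 6 h the count was 1102 without PI230970 Mock replicate 1, 404 without PI230970 Mock replicate 2, and 5 and 11 without Embrapa48 SBR replicates 2 and 3. At 18 h it was 0 without PI230970 SBR replicate 1, Embrapa48 SBR replicate 1 or Embrapa48 Mock replicate 1. It was 1 without PI230970 SBR replicate 2 or Embrapa48 SBR replicates 2 or 3, 7 without PI230970 Mock replicate 2 and 285 without Embrapa48 Mock replicate 3. At 36 h it was 0 without PI230970 SBR replicate 1 or Mock replicate 2 or Embrapa48 Mock replicate 2, and 3 without PI230970 Mock replicate 1. It was 2 without PI230970 SBR replicate 3, Embrapa48 SBR replicate 1 or Embrapa48 Mock replicate 1. The counts of 0 became 2 at 12 h without PI230970 Mock replicate 2, 3 at 48 h without Embrapa48 Mock replicate 2 and 23 at 168 h without Embrapa48 SBR replicate 2, and no other array moved them.

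In Mock plants the genotypes differed at many probe sets over the 10 times. IF7MaT (Entrez gene 100127426, chromosome 13, 14452393 to 14454559), an isoflavone 7-O-glucoside malonyltransferase, had a log2 level of 10.33 ± 1.00 in PI230970 and 6.32 ± 0.51 in Embrapa48 (SD, n = 30 each, 16.1-fold, SE of the log2 difference 0.09, adjusted p = 3.4e-58). GSTU28, a tau-class glutathione S-transferase, was at 6.44 ± 0.61 and 10.34 ± 0.98 (14.9-fold lower in PI230970, SE 0.09, adjusted p = 6e-55). Also higher in PI230970 at 10 of 10 times were BZIP94, a bZIP transcription factor, by 2.59 (SE 0.09; 4.13 and 1.40 with pseudocounts of 1 and 64, as its level of 4.58 in Embrapa48 is near the floor), MS by 2.07 (SE 0.35) and MYB139 by 1.91 (SE 0.20). Lower in PI230970 at 10 of 10 times were CYP28 (-3.31, SE 0.10) and KTI-2, a Kunitz trypsin inhibitor (-3.09, SE 0.27). AG1 was lower at 9 of 10 (-2.72, SE 0.27). The adjusted p ran from 9.6e-49 to 1e-06 for these 6. Of 36 probe sets of the jasmonate and lipoxygenase list 22 were lower in PI230970 and none higher (23 and none adjusted over the list alone). Of 61 of the isoflavonoid list 13 were lower and 1 higher (13 and 1 adjusted over the list alone). NAC factors had 14 of 30 higher and 1 lower (14 and 1 adjusted over the list alone), and WRKY factors 22 of 103 higher and 9 lower (19 and 9 adjusted over the list alone). MYB factors had 19 of 102 higher and 15 lower (19 and 14 adjusted over the list alone) and glutathione S-transferases 7 of 42 each way (7 and 7 adjusted over the list alone). With limma 12976 probe sets passed (34.5% of those tested), 6022 higher and 6954 lower in PI230970. Of the lists above, only the jasmonate and NAC lists held a larger share of called probe sets than this. The isoflavonoid, WRKY, MYB and glutathione S-transferase lists did not. The balance turned with the scaling, to 7981 and 5523 with the signals as deposited and 7172 and 5943 after quantile normalization. Arrays built on 1 reference sequence also read sequence differences between the genotypes. Without replicate 2, which holds 20 of the 60 Mock arrays, 7194 probe sets passed.

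Levels in Mock plants changed with time at most probe sets, with the clock genes among them. LHY, a morning-phased transcription factor of the circadian clock, had a mean log2 level of 13.08 ± 0.19 at 12 h and 13.02 ± 0.18 at 36 h (SD, n = 6), against 5.59 ± 0.46 at 24 h and 5.78 ± 0.36 at 48 h (adjusted p = 5.8e-62 for time). It was at 8.53 and 11.09 at 6 and 18 h. The other multiples of 24 h did not all repeat the low level of 24 and 48 h, with 6.38 at 72 h, 9.11 at 96 h, 9.31 at 120 h and 8.56 at 168 h. LCL3, of the same family, was at 10.75 ± 0.33 at 12 h, 10.54 ± 0.42 at 36 h, 4.77 ± 0.29 at 24 h and 4.91 ± 0.32 at 48 h, and between 4.89 and 5.36 from 72 h on (adjusted p = 3.8e-63). CAB3, a chlorophyll-binding protein, was at 11.08 ± 1.38 at 6 h and between 13.51 and 14.43 from 12 h on. By limma's F test 31691 of 37593 probe sets changed with time in Mock, among them 94 of 103 WRKY (94 adjusted over the list alone), 55 of 61 isoflavonoid (55 adjusted over the list alone) and 14 of 16 photosynthesis probe sets (14 adjusted over the list alone). Each rust comparison therefore uses the Mock arrays of its own time.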

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

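The tests along the leading axis of replicate spread, of the array that stood apart at 18 h and of splits for list differences alone were chosen after the result was seen, and the others before. The response to rust differed between the genotypes at 72 h for 31 probe sets, and for 1, 2 and 1 at 6, 18 and 36 h and 1 over the time course. The named differences at 72 h, PI230970 minus Embrapa48, were 3.89 for WRKY63, 3.82 for PRX4, 2.46 for 4CL4, 1.75 for CHI4A, 1.67 for STP, -2.00 for MYB186 and -1.66 for SFR2. Among 100 splits of the 12 arrays, 2 gave as many calls as the real 31, the highest other 119. At 6, 18 and 36 h 14, 35 and 20 splits did (real 1, 2 and 1, highest other 6, 904 and 337), and over the time course 16 (real 1, highest other 45), so chance cannot be excluded there. The 2 of 100 at 72 h do not exclude it either. That time had the most calls of the 10, and the share was not corrected for this choice. At 12, 24, 48, 96, 120 and 168 h the real count was 0 by limma, with 1332, 551, 761, 714, 674 and 2129 probe sets at an unadjusted p under 0.05, and all 100 splits gave as many (highest others 10, 1105, 116, 1, 3 and 36). The splits with 904, 1105, 337, 116 and 119 calls point to a structure of the samples at 18, 24, 36, 48 and 72 h.

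For the 31 probe sets at 72 h the tables argue against the technical explanations below as the whole cause. The leading axis of replicate spread, which holds 24% of the residual variance, left 89.3% of the median change when taken out (84 to 95.9 with single arrays left out), from a median of 2.13 to 1.91, although only 12 probe sets were then called, 9 of them among the 31. A part of the change still lies along it. Across all probe sets the change at 72 h correlated with the PR-10 end of the axis at 0.70 in PI230970 and -0.06 in Embrapa48, and their difference at 0.53. PI230970 Mock 72 h replicates 1 and 3 scored 59.3 and -51.2 on it. With single arrays left out the count of 31 ran from 0 (PI230970 Mock replicate 2 or Embrapa48 SBR replicate 2) to 82 (Embrapa48 Mock replicate 1). RNA integrity, read as the actin 3' to 5' ratio, accounted for a median of -2.35% of the change (quartiles -3.91 to 1.43). Without Embrapa48 Mock 72 h replicate 1, the array of highest ratio, 103% of the change was kept. Leaving out the centring of the arrays moved the median of all probe sets by 0.11, against a median change of 2.13 in the pattern, and only 2 probe sets were then called. A genotype-specific course of the response may explain the pattern but was not tested.

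At 18 h in Embrapa48, 441 probe sets were called, and the array Embrapa48 Mock 18 h replicate 3 stood apart. With the leading axis taken out 68% of the median change was kept (62.8 to 70.9 with single arrays left out), from 1.15 to 0.78, and 52 probe sets were called, 40 of them among the 441. Why the other calls ended was not tested. The change at 18 h correlated with the PR-10 end of the axis at 0.76 across all probe sets. Negative scores, such as the -78.7 of that Mock array, lie toward this end. An effect of the rust and array variation along the axis cannot be told apart for these probe sets, since the axis also carries PR-10. The state of that array is argued against as the cause, since 131% of the median change was kept without it (82.1 to 104 without each of the others). RNA integrity accounted for a median of -0.0985% (quartiles -1.34 to 1.38), which argues against it. Without that array 6028 probe sets were called, without Mock replicates 1 and 2 14 and 6, and without SBR replicates 1, 2 and 3 89, 258 and 60.

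The gene lists below passed camera for a difference of response, with medians of PI230970 minus Embrapa48. In the early window these were -0.35 for isoflavonoids (adjusted p = 2.3e-07, and adjusted p = 0.3 with an estimated correlation), 0.24 for ribosomal proteins (adjusted p = 0.00027, and adjusted p = 0.41 with an estimated correlation) and -0.21 for chaperones (adjusted p = 0.011, and adjusted p = 0.62 with an estimated correlation). In the middle window they were -0.09 for isoflavonoids (adjusted p = 0.014, and adjusted p = 0.68 with an estimated correlation), -0.53 for pathogenesis-related proteins (adjusted p = 3.7e-05, and adjusted p = 0.3 with an estimated correlation), -0.26 for NAC factors (adjusted p = 0.0019, and adjusted p = 0.51 with an estimated correlation) and 0.20 for photosynthesis (adjusted p = 0.0093, and adjusted p = 0.45 with an estimated correlation). In the late window they were 0.38 for peroxidases (adjusted p = 0.045, and adjusted p = 0.39 with an estimated correlation), -0.10 for jasmonate and lipoxygenases (adjusted p = 0.036, and adjusted p = 0.72 with an estimated correlation), 0.26 for ribosomal proteins (adjusted p = 0.00044, and adjusted p = 0.41 with an estimated correlation) and -0.24 for chaperones (adjusted p = 0.00027, and adjusted p = 0.41 with an estimated correlation). Between replicates 1 and 3 and replicate 2 the median changed sign for isoflavonoids in the early (-0.58 and 0.07) and middle window (-0.21 and 0.15) and for chaperones in the early window (-0.44 and 0.44). For these 11 calls of a difference, 11 of 30 random splits gave as many (highest other 18, median 8), so chance cannot be excluded. Over all 162 list tests, 1 of 30 splits, the real one, gave as many as 53 calls (highest other 48, median 27).

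Some control probe sets outside the comparisons were called between SBR and Mock. The 3 probe sets of a soybean cytochrome P450, placed on the array as a control, were higher in SBR at 12 and 168 h in Embrapa48, and the 3' and middle ones at 12 h in PI230970. The 3' set changed by 1.88 (SE 0.45, adjusted p = 0.0095) at 12 h in PI230970, and by 1.80 (SE 0.45, adjusted p = 0.0078) and 2.06 (SE 0.45, adjusted p = 0.0014) at 12 and 168 h in Embrapa48. The middle set changed by 2.04 (SE 0.50, adjusted p = 0.0095), 2.09 (SE 0.50, adjusted p = 0.0066) and 2.08 (SE 0.50, adjusted p = 0.0046), and the 5' set by 3.20 (SE 0.64, adjusted p = 0.00055) and 3.00 (SE 0.64, adjusted p = 0.0014) at 12 and 168 h in Embrapa48. The 5' set did not pass at 12 h in PI230970 (2.04, SE 0.64, adjusted p = 0.07). Of the 4 control probe sets called at 12 h in PI230970, the others were the 5' set of a control labelled GlutTrans (0.80, SE 0.20, adjusted p = 0.0097) and 1 labelled J01636 (-1.15, SE 0.33, adjusted p = 0.034). The last had a mean level of 4.95, near the floor, so its call is not read as a response to the rust. No explanation was tested.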

How the results depend on the processing

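Leaving out replicate 2, leaving out the 3 arrays of highest actin ratio, matching the lists by synonyms as well and the paired fit were chosen after the data were seen. Of the 58 named changes, all kept their direction under every alternative that tested them. For SBR against Mock the rule took genes whose 3 SBR arrays all lie above or below the 3 Mock arrays. Leaving out arrays could therefore not turn their direction. With the signals as deposited 47 of the 58 also kept their side of the threshold, and after quantile normalization 45. With log2(signal + 1) 38 did and with log2(signal + 64) 53. With the replicate block 56 did, without a trend in the variance 55, without the arrays of highest actin ratio 55, with only the arrays of the groups compared 26, without replicate 2 19, and among the probe sets above the median mean level 34 of those tested there, while 1 did not. With 1 array left out at a time, named changes kept the call in 186 tests and lost it in 156.

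The counts moved by more than 1.5 times as follows, and except where a reason is given the cause was not tested. With log2(signal + 1) they were 14 at 6 h, 1 at 18 h, 0 at 24 h, 6 at 36 h, 6 at 120 h, 11 at 168 h in PI230970, 6 at 6 h, 1 at 24 h, 7 at 48 h, 9 at 72 h in Embrapa48 and 1 at 18 h, 4 at 36 h, 6 at 72 h, 1 at 96 h in the difference between genotypes. With log2(signal + 64) they were 2 at 18 h, 1 at 48 h, 25 at 72 h, 6 at 96 h in PI230970, 4 at 6 h, 7 at 72 h in Embrapa48 and 4 at 6 h, 1 at 12 h, 3 at 36 h, 8 at 168 h, 3 over the time course in the difference between genotypes. With the signals as deposited they were 0 at 6 h, 4 at 24 h, 0 at 72 h in Embrapa48 and 0 at 36 h, 2 at 72 h, 2 over the time course in the difference between genotypes, and after quantile normalization 14 at 6 h, 1 at 96 h in PI230970, 2 at 24 h, 0 at 72 h in Embrapa48 and 3 at 72 h, 2 over the time course in the difference between genotypes. Among only the probe sets above the median mean level, where fewer were tested, they were 3 at 6 h, 594 at 12 h, 0 at 24 h, 2 at 72 h, 0 at 96 h, 2 at 120 h, 4 at 168 h, 194 over the time course in PI230970, 2 at 6 h, 0 at 24 h, 4 at 36 h, 4 at 48 h, 0 at 72 h, 0 at 120 h, 245 at 168 h, 533 over the time course in Embrapa48, 0 at 6 h, 0 at 18 h, 14 at 72 h, 0 over the time course in the difference between genotypes, 8517 for the genotype difference in Mock and 18179 for time in Mock. Without a trend in the variance they were 4 at 24 h in Embrapa48 and 2 at 36 h in the difference between genotypes, and with an absolute log2 change of at least 1, a stricter rule, 3 at 72 h in PI230970, 274 at 18 h in Embrapa48 and 852 for the genotype difference in Mock. With only the arrays of the groups compared, which leaves fewer arrays for the spread, they were 0 at 6 h, 222 at 12 h, 0 at 24 h, 0 at 72 h, 62 at 96 h, 0 at 120 h, 13 at 168 h in PI230970, 18 at 6 h, 426 at 12 h, 0 at 18 h, 0 at 24 h, 20 at 36 h, 0 at 48 h, 0 at 72 h, 0 at 120 h, 0 at 168 h in Embrapa48 and 0 at 6 h, 0 at 18 h, 0 at 36 h, 1 at 72 h in the difference between genotypes. Without the 3 arrays of highest actin ratio they were 1826 at 6 h, 13 at 72 h, 1 at 96 h, 548 over the time course in PI230970, 709 at 18 h, 9 at 72 h in Embrapa48 and 1236 at 6 h, 97 at 72 h, 3 over the time course in the difference between genotypes.

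Residuals of SBR and Mock arrays of the same replicate number correlated at a median of 0.085 over 60 pairs, above 0.1 in 27, and 64 of 120 arrays were closest to their own number. Each array was set against 3 of the other treatment, so chance gives 1 in 3, and 64 of 120 is above that share. All 3 pairs were above 0.1 in 3 of 20 comparisons, at 24 and 120 h in PI230970 and 48 h in Embrapa48. A paired fit moved the counts there to 0 (limma, 944 with an unadjusted p under 0.05), 25 and 10, the last not by more than 1.5 times. Elsewhere not all 3 pairs were above 0.1, but replicate 2 is a batch by its poly-A spike levels. With the replicate number as a block over all arrays, the counts moved to 10 at 72 h in PI230970 and 2 at 36 h in the difference between genotypes. In Embrapa48 they moved to 697 at 18 h (336 higher and 361 lower), 3 at 24 h and 63 at 72 h (49 higher and 14 lower). No other count moved.

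With 1 array or 1 replicate number left out, the counts ranged over 7194 to 12374 for the genotype difference in Mock, 36 to 174 over the time course, 0 to 1661 at 6 h, 21 to 1300 at 12 h, 0 to 3 at 18 h, 0 to 4 at 24 h, 0 to 3 at 36 h, 0 at 48 h, 0 to 62 at 72 h, 0 to 1 at 96 h, 3 to 184 at 120 h, 6 to 25 at 168 h in PI230970, 215 to 1503 over the time course, 0 to 6 at 6 h, 106 to 922 at 12 h, 0 to 6028 at 18 h, 0 to 60 at 24 h, 0 to 13 at 36 h, 0 to 37 at 48 h, 0 to 842 at 72 h, 0 to 3 at 96 h, 1 to 13 at 120 h, 181 to 520 at 168 h in Embrapa48, 0 to 1 over the time course, 0 to 1102 at 6 h, 0 to 2 at 12 h, 0 to 285 at 18 h, 0 at 24 h, 0 to 3 at 36 h, 0 to 3 at 48 h, 0 to 82 at 72 h, 0 at 96 h, 0 at 120 h, 0 to 23 at 168 h in the difference between genotypes and 27816 to 29032 for time in Mock.

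Of the 162 list tests the 53 calls with the preset correlation became 5 with an estimated correlation, 17 by fry and 57 without replicate 2. The same 53 tests kept the call with the replicate block, 52 after quantile normalization, 52 without the arrays of highest actin ratio, 50 with log2(signal + 64), 50 with lists matched by synonyms too and 36 among the probe sets above the median mean level, where 2 did not. The direction of 1 reversed: the NAC list in the middle window in PI230970 pointed upward without replicate 2 (adjusted p = 0.78). The cause was not tested. The 3 alternatives planned for probe sets of other organisms were not run, since the identifiers on this array show none, and the fit to only the arrays compared has no value of its own for the difference over the time course, which uses all arrays. The level of a probe set limits small changes: a simulated log2 change of 1 was recovered in 62.2% and 65.4% of probe sets above the median level and 36.4% and 27.1% below it, at 12 h in PI230970 and 168 h in Embrapa48. One of 2 was recovered in 94.4% and 92.2% above it and in 100% and 93.9% below it.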

Other observations

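The test of fungal RNA, the averages over 96 to 168 h and the splits that part pairs were chosen after the result was seen. Averaged over 96 to 168 h, single probe sets were higher under rust in both genotypes, and no gene list was tested for these times. OLPa changed by 2.31 in PI230970 and 3.13 in Embrapa48 (adjusted p = 2.4e-07 and 4e-12), PR-10 by 2.13 and 3.26 (0.0014 and 2.9e-08), GSTU42 by 1.94 and 2.36 (4e-05 and 1.9e-07), PR1-1 by 1.46 and 1.56 (3.5e-06 and 4.5e-07) and WRKY4 by 0.42 and 0.43 (0.0018 and 9e-04). With limma 122 probe sets were higher and 2 lower in PI230970 and 213 and 9 in Embrapa48, and 99 of the higher ones were shared, where 0.691 would be if the sets were independent. The difference of these averages between the genotypes passed for 0 probe sets, with 1421 at an unadjusted p under 0.05. Over the whole late window of 72 to 168 h the order was the opposite, with 257 higher and 6 lower in PI230970, 80 and 4 in Embrapa48, and 67 of the higher ones shared (0.547 if independent). The difference passed there for 1 probe set, which was lower in PI230970.

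Of the named genes on the leading axis of replicate spread within groups, PR-10 lies at 1 end with NAC1, CHIA1, CYP81E11, PT01, MS, MYB139 and NAC34, and at the other end SBPRP, GASA14, GASA11, GER16, EXP4, GASA6, PIP1-6 and BZIP50, among them expansin, gibberellin-regulated and aquaporin family members. Negative scores lie toward the PR-10 end and positive ones toward the other. The largest scores were those of PI230970 Mock 6 h replicate 3 (98.9), Embrapa48 Mock 48 h replicate 1 (83.8), PI230970 Mock 24 h replicate 1 (81.7) and Embrapa48 Mock 18 h replicate 3 (-78.7). Embrapa48 SBR 48 h replicate 1 (69.8), PI230970 Mock 6 h replicate 1 (-65.5) and PI230970 SBR 24 h replicate 1 (61.2) followed. Across probe sets, which are not independent, the change under rust correlated with the PR-10 end at -0.50 (6 h in Embrapa48) to 0.77 (6 h in PI230970), at 0.49 and 0.21 at 12 h in PI230970 and Embrapa48, 0.76 at 18 h in Embrapa48 and 0.70 at 72 h in PI230970.

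The 425 probe sets that rose at 168 h in Embrapa48 could include ones that read RNA of the fungus, which would be most abundant late in a susceptible plant. As the whole cause this is argued against, since 40.5% of them (172) have a soybean gene in the annotation against 24.1% of all probe sets (Fisher exact p = 5.6e-14), and fungal RNA in a part of them stays open. The test takes probe sets as independent, which they are not. The argument holds only if probe sets with a soybean gene do not read fungal RNA, which was not tested. RNA integrity accounted for a median of 1.54% of the change (quartiles -0.713 to 3.81), which argues against it.

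Splits of the arrays were counted for the other comparisons. For the F test over the time course in PI230970, 1 of 100 splits gave as many calls (real 333, highest other 300). Chance is excluded there at a share of 0.05. In Embrapa48 4 of 100 did (real 890, highest other 1030). That share is under 0.05, but too near it for 100 random splits to exclude chance. Chance is excluded for the genotype difference in Mock (1 of 100, real 12976, highest other 313) and for time in Mock (1 of 100, real 31691, highest other 12518). For SBR against Mock at 1 time the 10 splits are too few for a share under 0.05. In PI230970 the real counts and the highest others were 9 and 159 at 6 h (3 splits as large), 952 and 68 at 12 h (1), 0 and 30 at 18 h (10), 1 and 776 at 24 h (4), 0 and 102 at 36 h (10), 0 and 3 at 48 h (10), 5 and 9 at 72 h (2), 2 and 2 at 96 h (2), 16 and 26 at 120 h (2), and 32 and 1 at 168 h (1). In Embrapa48 they were 1 and 0 at 6 h (1), 821 and 253 at 12 h (1), 441 and 1508 at 18 h (4), 8 and 79 at 24 h (3), 13 and 1 at 36 h (1), 11 and 1232 at 48 h (4), 1 and 7 at 72 h (3), 0 and 0 at 96 h (10), 8 and 0 at 120 h (1), and 456 and 123 at 168 h (1). The counts of 0 are by limma, where 933, 1193, 663 and 1133 probe sets had an unadjusted p under 0.05. Splits with more calls than the real one and at least 30, at 6, 18, 24 and 36 h in PI230970 and at 18, 24 and 48 h in Embrapa48, point to a structure of the samples within these groups. At 24 and 120 h in PI230970 and 48 h in Embrapa48, where the replicate numbers pair the arrays, the 4 splits that part all 3 pairs gave 1, 16 and 11 for the real split and 0 by limma for the others. The high counts of 776, 26 and 1232 there came from splits that keep a pair together.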
